A study of Mus musculus with 40 samples.

How the data were processed

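Transposon insertions were mapped in 4 groups of mouse astrocytes, male and female, each with HyPBase fused to Brd4 or unfused. Reads were aligned to mm10, and Bowtie2 2.3.4.3 and MACS2 are named without a role, per the submitters' processing notes; filters and the way nearby reads were joined into 1 insertion are not given in the sources used here. The 7 deposited insertion files give, per insertion, its position, strand, read count and a 9-base barcode, per the labels and the values in the files. Read counts were made by the authors and were not normalized. The deposited peak lists hold counts of insertions per peak for male and female Brd4 wells, and corrected p-values from the authors that are not capped at 1, which were used only to describe the lists. From the values, peaks were called on the pooled Brd4 insertions of both sexes. Recounting the insertion files gave the deposited count in all 29852 peaks for both sexes.

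An insertion was counted once per position, strand and barcode, whatever its reads, since reads of 1 insertion are copies of it. A barcode was taken as a well, as no file held more barcodes than the labels give it samples. Barcodes carry no replicate number. The file's group came from the samples whose description names the file. The pair of male Brd4 barcodes that shared over 0.5 of the smaller set's sites was merged, leaving 39 wells. Well depth ran from 30199 to 239134 insertions. In regions with a mean of at least 10 insertions per well of the group, wells of a group varied less than counting error. The median chi-square per degree of freedom was 0.494 in male Brd4 (2449 regions) and 0.523 in female Brd4 (2481). It was 0.563 in male unfused (1925) and 0.810 in female unfused wells (426). Sites recurred between wells, and a median of 39.8% of a well's positions were shared within male Brd4, 39.2% within female Brd4 and 33.9% between the sexes, so recurrence was not confined to a group. The files do not settle whether wells shared material or reads crossed between barcodes; if so, the SDs and p-values between wells understate the spread between separate transfections. Counts of unique sites are bounded by the sites available, which narrows differences in dense regions.

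Regions were the 29852 deposited peaks, none of which touched another. Genes of regions are those the deposited lists pair with them. Gene windows were 34610 genes with 10 kb to each side, from a RefSeq gene table of GRCm38.p6, the same assembly as mm10. Of 11471 genes also placed in the deposited lists, 99.4% overlapped on the same chromosome. Counts per region and well were tested with edgeR 4.0.16 (quasi-likelihood, default filter at a minimum count of 10) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05. Library size was all insertions of a well. TMM factors were used between sexes and for the interaction and not between fusion and unfused, where a factor that centres the regions would hide a shift of all insertions. The interaction used all 4 groups. A group at 0 was compared at 3 insertions over the group.

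Gene lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and fry as alternatives. Shares of insertions in peaks and per chromosome were compared with two-sided permutation tests, exact where a group had fewer than 10 wells and otherwise with 100000 resamples (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). Figures were drawn with matplotlib 3.10.9.

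Before the data were examined, the tests, the 23 gene lists and the rule for named items were fixed. Among autosomal regions past the threshold with an absolute log2 fold change of at least 1, the 12 with the smallest p per direction were named for Brd4 between sexes, 6 for the interaction and for unfused wells, and 8 for fusion against unfused, skipping a gene already taken. Up to 4 members per tested list were named by p, besides Nf1, Trp53, Xist, Brd4, Myc and the Y-linked genes. Members named outside this rule in the account of lists (such as Dlx1, Meis2, Foxg1 and the members of lists too small to test) were chosen after their values were seen.

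Alternatives covered library size without TMM, DESeq2 1.42.0, no filter or a minimum count of 2, insertions with at least 2 reads, bins of 10 kb, wells of each file set (mBC or pBC), file set as a block, offsets for the unfused ratio per chromosome or per 5 Mb, a test against a fold of 1.5, wider gene windows of 50 kb, and fits without the 2 shallowest female unfused wells or without the shallowest well of each group. The last 2, the filter at 2, sites found in 1 well only, the merged barcodes kept apart, offsets from insertions outside peaks or without a filter, and the tool, filter, scaling and file set alternatives for gene windows were added after the data were seen. Tests were checked on simulated counts drawn from the real means and depths. Simulated wells were independent, at a dispersion of 9.77e-05, which is near counting error. Real wells varied less and may share material, so recovery and false calls need not carry over to them. For Brd4 between sexes, 66.0% of regions changed 1.5-fold and 100% of those changed 2-fold and 4-fold were recovered among 2518 tested, with 9 false calls. For unfused wells 86.7% were recovered at 1.5-fold among 586, with 14 false calls. For fusion against unfused, 83.6% in male cells (1589 tested) and 84.2% in female cells (1509) were recovered at 1.5-fold, with 6 and 8 false calls, and the interaction had 4 among 2700. The deposited lists of gene symbols were not used, as they hold no values.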

Results

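Insertions of a piggyBac transposon were mapped in male and female mouse astrocytes that carry null alleles of Nf1 and p53 and serve as a model of glioblastoma. In this assay, called transposon calling cards, the transposase HyPBase leaves a self-reporting transposon near the place where it is held, and the transposon's RNA is sequenced to find that place. HyPBase was either fused to Brd4, a bromodomain protein that binds acetylated histones at active enhancers and promoters, or left unfused, which records where the transposase inserts on its own. The study's title asks whether Brd4-bound enhancers differ between the sexes. The labels describe 40 samples in 4 groups of 10, each sample a transfected well selected with puromycin at 2.5 ug per ml for 3 days, and the insertion files hold 40 barcodes. The sample titles name 1 culture per sex, so the wells are repeats within a culture, p-values measure only the spread between wells, which may be technical, and sex and culture are confounded in every comparison below.

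In all, 5442484 unique insertions (position, strand and barcode) were recorded. A pair of male Brd4 barcodes shared 79719 sites, 84.8% of the smaller set, against a median of 36.1% for pairs of barcodes in that group, and was counted as 1 well. The 9 male Brd4 wells then held 94563 to 138016 insertions each (1140633 in total) and the 10 female Brd4 wells 116968 to 147505 (1327030). The 10 male unfused wells were the deepest, with 126690 to 239134 insertions (2047401), and the 10 female unfused wells the shallowest, with 30199 to 109730 (847701). Values are given as insertions scaled to 1000000 per well (IPM), as mean ± SD over wells with n = 9 for male Brd4 and n = 10 for each of the other groups. A count of 0 over a whole group allows up to 2.63 IPM in male Brd4, 2.26 in female Brd4, 1.47 in male unfused and 3.54 in female unfused wells, from 3 insertions and for counting error only.

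The Y chromosome separated the sexes in each kind of well. Male wells held 11 to 32 Y insertions with Brd4 and 16 to 53 without it, and female wells held 0 to 4 and 0 to 2. The windows of Uty, Kdm5d, Eif2s3y and Ddx3y, Y-linked genes that are widely expressed, held 51, 30, 38 and 43 insertions over the male Brd4 wells and 0 over the female ones. Uty was thus at least 19.8-fold higher in male wells. Usp9y held 3 male insertions and Sry 1, too few to compare. At Xist, the RNA gene that silences 1 X chromosome in female cells, female Brd4 wells held 94.9 ± 18.0 IPM and male wells 60.4 ± 13.6 (log2 fold change of male over female −0.75, edgeR adjusted p = 0.000838). With 50 kb to each side of Xist, the log2 fold change was −0.13 and did not pass (adjusted p = 0.229). The unfused wells of the sexes held 29.8 ± 15.9 and 29.6 ± 9.90 IPM there. At the loci that the labels call null and at 2 fixed reference genes, no difference passed the test without a count filter. Male and female Brd4 wells held 223 ± 31.6 and 181 ± 35.2 IPM at Nf1 (adjusted p = 0.285), 55.6 ± 16.9 and 43.5 ± 12.0 at Trp53 (0.524), 38.2 ± 16.4 and 31.4 ± 16.9 at Brd4 (0.786), and 114 ± 19.8 and 94.8 ± 23.7 at Myc (0.541). Insertions in a gene window say nothing about whether the gene's protein is made.

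The Brd4 fusion raised the share of insertions inside the 29852 deposited peaks, which the authors called on the Brd4 insertions of both sexes pooled. In male cells the share of insertions in peaks was 84.8 ± 0.627% with Brd4 and 50.1 ± 0.848% without it, a difference of 34.7 percentage points (two-sided exact permutation test, p = 2.2e-05, the smallest it can give). In female cells it was 83.7 ± 0.472% and 56.7 ± 2.13%, a difference of 27.0 points (permutation test, p = 2e-05, the smallest it can give). Without the 2 shallowest female unfused wells, that female unfused share was 55.8 ± 1.04% (n = 8). Between the sexes, the Brd4 share was 1.11 points higher in male wells (exact permutation test, p = 0.00043). Among insertions with at least 2 reads, that difference was 0.07 points (p = 0.84 by the same exact test). The unfused share differed by −6.55 points, male less female (permutation test, p = 2e-05). The shallowest wells of each unfused group had its highest shares, 60.9% and 59.7% in the 2 shallowest female wells and 52.1% in the shallowest male well. Male unfused wells were deeper than female ones, so depth and sex were not separated in this difference or in the fusion effects. Since the peaks were called on the Brd4 insertions, their share in Brd4 wells is not independent of the peak calls.

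**Figure D1:**
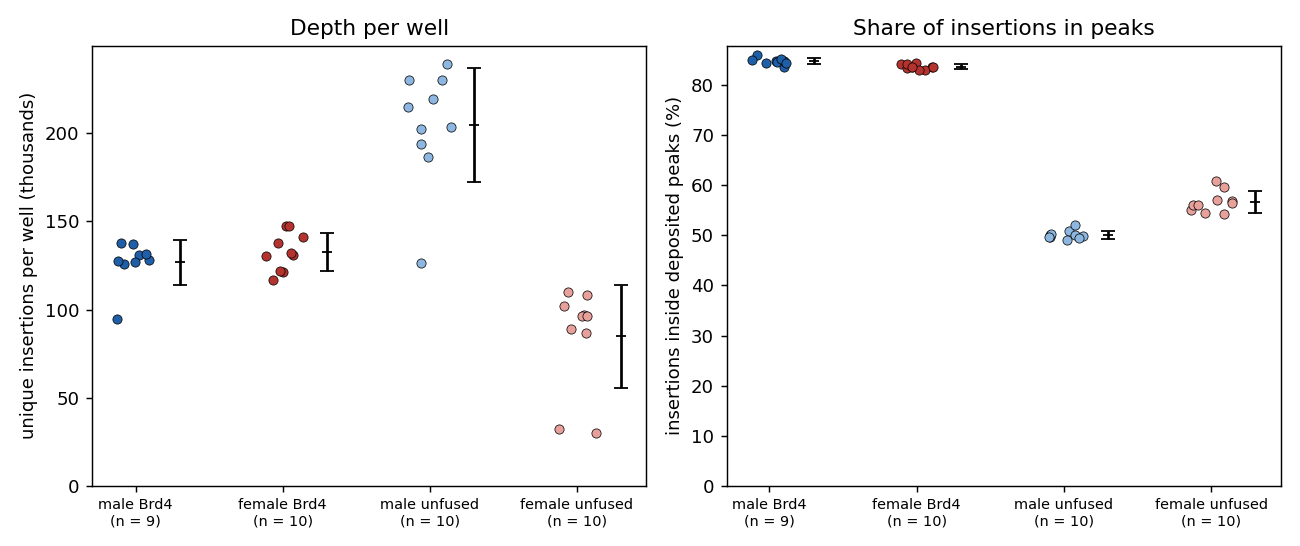
Unique insertions per well (left, axis in units of 1000) and percent of a well's insertions inside deposited peaks (right) for the 4 groups. Points are wells and bars are the mean ± SD. Brd4 wells of both sexes lie near 84%, male unfused wells near 50.1% and female unfused wells near 56.7%, and 2 female unfused wells, with 30199 and 32249 insertions, stand below the rest.

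In male cells, the 8 named regions, 7 of which overlap a gene, held more insertions when Brd4 was fused than when it was not. The region with the smallest p lay on chromosome 10 at 120621420 to 120629954 (mm10, as are all positions), outside a gene and 135778 bp from 4921513I03Rik, and rose from 194 ± 27.0 to 627 ± 53.2 IPM (log2 fold change 1.71, SE 0.07). The region over Hist1h3c, in a cluster of histone genes on chromosome 13, rose from 234 ± 36.01 to 699 ± 70.9 IPM. A region within Adk, the gene of adenosine kinase, rose from 181 ± 22.6 to 564 ± 49.6 IPM, and a region at the start of Cp, the gene of the copper carrier ceruloplasmin, from 188 ± 15.2 to 559 ± 58.2. Regions at Cyth3, an exchange factor of ARF GTPases, and at the uncharacterised loci Gm12603, 3110039I08Rik and AI839979 rose as well, with log2 fold changes of 1.90, 1.40, 1.68 and 1.49. Of 1804 regions tested with edgeR's quasi-likelihood test, scaled to all insertions of a well, 1722 rose and 2 fell. When factors that centre the regions (TMM) were used, 285 rose and 315 fell, so the direction of most calls rests on scaling to all insertions. Without the shallowest well of each group, 2646 of 2930 tested regions passed, as more regions passed the count filter.

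In female cells the same rule named other regions, all 8 of them on the deposited female-biased list. That list was chosen on the same female Brd4 wells, and all regions are peaks called on Brd4 insertions. Rises over unfused wells, here and in male cells, are therefore not independent of the choice of regions. A region on chromosome 18 at 69124981 to 69134956, 102708 bp from Mir145b, rose from 78.3 ± 33.5 to 538 ± 59.2 IPM (log2 fold change 2.75, SE 0.13). A region just inside the 5' end of Dkk2, which encodes a secreted modulator of Wnt signalling, rose from 62.1 ± 25.5 to 434 ± 44.5 IPM. A region within Gmds, a gene of GDP-fucose synthesis, rose from 94.3 ± 35.9 to 492 ± 70.4 IPM. A region 16227 bp from Tcaf3 rose from 38.1 ± 25.7 to 297 ± 32.6, and a region 30993 bp from Gm17750 from 24.9 ± 19.1 to 294 ± 46.6. The region nearest to Mir466h rose from 51.0 ± 23.1 to 403 ± 69.6 IPM, that nearest to Fam181b, 1051109 bp away, from 40.3 ± 14.4 to 315 ± 33.5, and that nearest to Tars from 63.7 ± 30.2 to 333 ± 22.9. Of 1509 regions tested, 1191 rose and 25 fell, and with TMM factors 357 rose and 362 fell. DESeq2, with its own size factors and no count filter, gave 1674 that rose and 1281 that fell in female cells, and 972 and 1726 in male cells. With the same scaling to all insertions, the gene windows of the regional forebrain and patterning list rose in 10 of 12 tested members in male cells and fell in 1 (camera adjusted p = 0.0109, and 0.224 with an estimated correlation). Over all 4014 gene windows tested in male cells, 1937 rose and 861 fell. In female cells 5 of 17 members rose and 1 fell (camera adjusted p = 0.959), while 1235 of all 2898 windows rose and 477 fell. No other list passed this test in either sex.

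With Brd4 fused, male cells held more insertions than female cells at a set of loci led by the Nkx2-1 locus. Nkx2-1 encodes a homeobox factor of the ventral forebrain. The region with the smallest p, on chromosome 12 at 56507042 to 56514712, lay in Sfta3-ps, 17223 bp from Nkx2-1. It held 387 ± 28.1 IPM in male wells and 0 insertions in all 10 female wells, at least 170-fold higher in male wells (edgeR adjusted p = 1.34e-35). A region within Meis2, a homeobox gene (chromosome 2, 116042185 to 116050238), held 590 ± 56.4 IPM in male and 167 ± 16.9 in female wells. A region at Cyp1b1, whose product hydroxylates estradiol among other substrates (chromosome 17, 79705256 to 79713000), held 322 ± 29.0 and 29.6 ± 17.0 IPM. A region at the start of Runx2, the transcription factor of bone formation, held 247 ± 37.4 and 17.1 ± 9.42, and also overlaps Supt3.

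Further named regions were higher in male Brd4 wells. Within Ptprn2, a receptor-type phosphatase gene, 231 ± 30.3 IPM were found in male wells and 2 insertions over all female wells. At Trhr, the receptor of thyrotropin-releasing hormone, male wells held 251 ± 24.1 and female wells 17.5 ± 13.2 IPM. At Nalcn, a sodium leak channel gene, they held 512 ± 37.7 and 195 ± 25.97, and at Akap6, a kinase anchoring protein gene, 357 ± 32.7 and 66.9 ± 22.8. The region within Adk held 564 ± 49.6 and 217 ± 29.9 IPM. That within Sox2ot, the transcript that spans Sox2, held 493.1 ± 35.2 and 199 ± 19.1, that near Vamp4 held 241 ± 27.7 and 34.0 ± 10.7, and that at Dock8 held 292 ± 37.0 and 62.1 ± 13.6.

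Female cells with the Brd4 fusion held more insertions at regions near Zic genes, Sp8 and Dlx1, which encode transcription factors. On chromosome 9, between the genes Tbc1d2b and Zic1, a region at 91128363 to 91136985 (223360 bp from Zic1) held 716 ± 67.4 IPM in female and 87.6 ± 16.6 in male wells, and a region at 90699320 to 90707472 (428551 bp from Tbc1d2b) held 825 ± 82.9 and 126 ± 21.5. A region over the start of Sp8 (chromosome 12, 118837815 to 118848117) held 549 ± 47.2 IPM in female and 44.3 ± 19.2 in male wells. The region that the deposited list pairs with Mir5098 (chromosome 2, 71529836 to 71540621) overlaps Dlx1 and lies 2787 bp from Dlx2, and held 414 ± 40.8 and 16.9 ± 8.98 IPM. A region within Clybl on chromosome 14, 73400 bp from Zic5 and 89624 bp from Zic2, held 508 ± 52.1 and 77.4 ± 21.4.

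The region with the smallest p of the comparison, on chromosome 7 at 70168043 to 70178359 and 509 bp from Gm29683, held 852 ± 69.7 IPM in female wells and 6.02 ± 5.20 in male wells (log2 fold change of male over female −6.97, SE 0.13, adjusted p = 2.43e-47). Near-absence from male wells was also seen at Dkk2 (434 ± 44.5 against 5.37 ± 5.51 IPM), Gmds (492 ± 70.4 against 6.33 ± 7.74) and near Tcaf3 (297 ± 32.6 against 3.34 ± 5.38). Within Sema3a, the gene of a secreted axon guidance factor, female wells held 411 ± 44.7 and male wells 34.6 ± 15.9 IPM. A region 435917 bp from Ccnh held 851 ± 68.1 and 151 ± 31.2, and a region near Gm13710 held 308 ± 24.4 and 22.8 ± 9.30.

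Of 2657 regions tested, 1653 differed between male and female Brd4 wells, 801 higher in male and 852 higher in female wells. Scaled to all insertions in place of TMM, 897 were higher in male and 790 in female wells, and without a count filter 3644 and 4980, so the balance of directions depends on these choices. By at least 2-fold, 248 were higher in male and 438 in female wells. When the region's unfused ratio in its 5 Mb window was taken out as an offset, 1600 regions passed, 1308 of them calls of the main test with the same direction, while the region near Tbc1d2b turned to a log2 fold change of 0.15 and that near Zic1 no longer passed. That offset contains the unfused insertions of the segment itself.

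**Figure D2:**
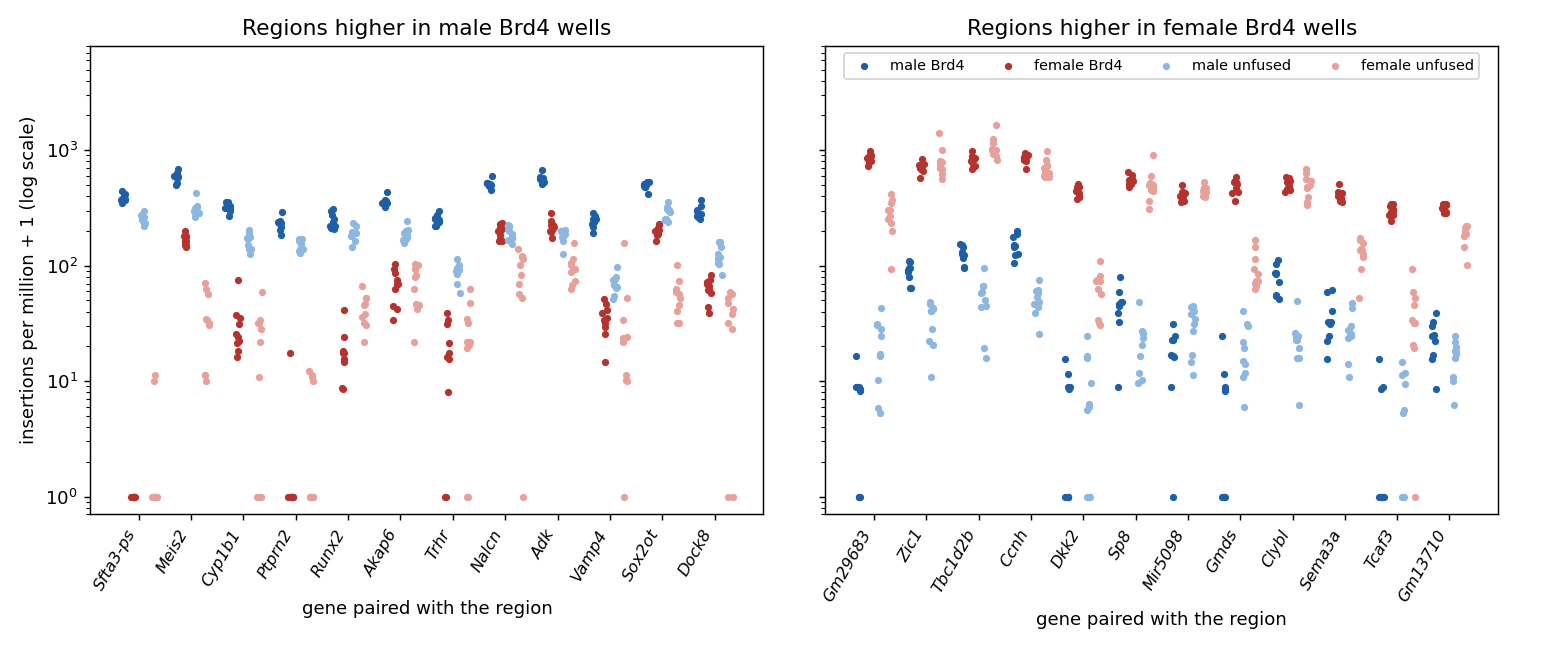
IPM plus 1 on a log axis in each well, at the named regions higher in male (left) or female (right) Brd4 wells. Points are wells of the 4 groups. At Sfta3-ps the female Brd4 wells sit at 0 insertions and male wells average 387, and at most regions the paler unfused wells differ in the same direction as the Brd4 wells.

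The gene-level comparisons of the sexes use Brd4 wells only and do not separate the fusion from the transposase alone. At gene level, in windows of the gene body and 10 kb to each side, the regional forebrain and patterning factors were the list that passed at camera's preset correlation. Of 33 members 18 were tested, of which 12 were higher in female Brd4 wells, 5 in male Brd4 wells and 1, Foxg1, did not pass (1453 ± 139 against 1343 ± 75.9 IPM). Higher in female wells were Zic4 (1586 ± 114 against 183 ± 37.5 IPM), Zic1 (766 ± 75.5 against 60.1 ± 26.2), Zic2, Sp8 (724 ± 55.9 against 62.2 ± 25.5), Dlx1 (516 ± 42.2 against 51.4 ± 20.3), Dlx2, Pax6 (260 ± 30.3 against 40.9 ± 13.9), Emx2, Lhx2, Otx1, Otx2 and Six3. Higher in male wells were Nkx2-1 (517 ± 31.5 IPM against 0 insertions, at least 228-fold), Meis2 (2535 ± 138 against 1141 ± 84.9), Meis1, Nr2f1 (714 ± 56.4 against 393 ± 47.0) and Nr2f2. In unfused wells the mean of each of these called genes differed between the sexes in the same direction. Female and male unfused wells held 734 ± 143 and 37.9 ± 13.3 IPM at Sp8, 562 ± 25.9 and 65.5 ± 11.3 at Dlx1, and 448 ± 146 and 1835 ± 164 at Meis2. Most of these factors mark different regions of the embryonic forebrain. The windows of Zic1 and Zic4 overlap, as do those of Dlx1 and Dlx2, so each pair shares insertions. The list's median log2 fold change was −1.45, also with Nkx2-1 at its bound (camera adjusted p = 0.00509 over 13 lists; adjusted p = 0.606 with an estimated correlation). Adjusted over the list alone, the counts were again 12 and 5. With the unfused ratio of the 5 Mb window taken out, 12 and 4 passed and the median was −0.84; Zic4 then had a log2 fold change of −0.32 and Zic1 of −0.87, in place of −3.22 and −3.76.

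The integrin and extracellular matrix genes did not pass as a list (camera adjusted p = 0.792). Of 18 tested, 7 were higher in female and 4 in male Brd4 wells, and 9 and 4 adjusted over the list alone. Itga1, a collagen-binding integrin chain, held 454 ± 32.4 IPM in female and 54.7 ± 24.7 in male wells, and Itgb1, its partner chain, 522 ± 47.7 and 190 ± 18.9. Tenascin C (Tnc) held 242 ± 35.3 and 93.3 ± 30.8, and thrombospondin 1 (Thbs1) 187 ± 24.2 and 84.2 ± 24.0. Among astrocyte identity genes, 3 of 7 were higher in female and 2 in male wells. Nfia, a factor that promotes gliogenesis, held 1105 ± 67.4 IPM in female and 479 ± 42.9 in male wells, while Sox9 held 73.3 ± 18.9 and 155 ± 32.4 and Gja1 81.0 ± 12.9 and 125 ± 29.2. Sox9 and Gja1 no longer passed when the unfused ratio of the 5 Mb window was taken out. Nfib was higher in female wells (1339 ± 119 against 1223 ± 113), and turned to the opposite direction (log2 fold change 0.34) with that offset.

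In the cell cycle list, 3 of 11 were higher in male and 2 in female wells. Cdk6 held 291 ± 39.0 IPM in male and 113 ± 31.0 in female wells, and Cdkn2c, an inhibitor of Cdk4 and Cdk6, 416 ± 61.9 and 857 ± 47.6. Ccnb1 held 93.3 ± 24.7 and 124 ± 11.8 and no longer passed with 50 kb flanks, and Rb1, which held 639 ± 67.2 and 506 ± 53.8, turned direction with the 5 Mb offset (log2 fold change −0.34). At Cdk6, male and female unfused wells held 284 ± 38.1 and 145 ± 56.3 IPM. Fusion against unfused did not pass there in either sex (log2 fold changes 0.03 and −0.40, without a count filter), while Cdkn2c rose in both (0.59 and 0.64). In the RTK and Ras list, 5 of 15 were higher in female and 2 in male wells. Egfr held 190 ± 35.8 IPM in female and 46.7 ± 12.9 in male wells, Raf1 99.0 ± 21.9 and 45.4 ± 18.7, Dusp4 148 ± 24.3 and 94.1 ± 25.9, and Hbegf 163 ± 22.2 and 268 ± 20.9. In the TGF-beta and BMP list, 4 of 14 were higher in female and 2 in male wells, among them Bmpr1b, a BMP receptor (186 ± 32.5 in female, 31.4 ± 16.1 in male), Skil (129 ± 24.1 and 73.5 ± 33.6), Smad6 (182 ± 22.9 and 138 ± 16.5) and Id4 (77.8 ± 16.5 and 147 ± 30.7).

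In the neural and glioma stem cell list, 3 of 11 were higher in female wells and none in male wells. They were Pax6 and Lhx2, which also belong to the patterning list, and Hes1 (326 ± 26.1 in female, 243 ± 22.8 in male). Sox4 held 84.7 ± 16.1 and 118 ± 35.2 and did not pass (adjusted p = 0.0651). Of 12 mesenchymal genes, 4 were higher in female and 2 in male wells, and 4 and 1 adjusted over the list alone. Zeb2 held 368 ± 57.4 IPM in female and 552 ± 45.0 in male wells, and Tead1 611 ± 51.4 and 489 ± 41.2; Tead1 no longer passed with the 5 Mb offset (log2 fold change −0.17, adjusted p = 0.059). Cdh2 (1303 ± 102 and 1088 ± 67.0) and Runx1 (649 ± 31.8 and 589 ± 51.2) turned direction with the 5 Mb offset, to log2 fold changes of 0.39 and 0.08. Of 6 AP-1 and immediate early genes, Ier2 (198 ± 27.9 in male, 124 ± 24.2 in female) and Klf6 (303 ± 50.7 and 233 ± 36.1) were higher in male wells. Klf6 no longer passed with the 5 Mb offset (adjusted p = 0.547), with DESeq2 (0.127), in windows with 50 kb flanks (0.186) or without a count filter, among others. Ier3 and Junb did not pass.

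Of 5 p53 targets, Sesn2 (143 ± 26.1 in female, 89.0 ± 17.6 in male) and Zmat3 (162 ± 41.8 and 120 ± 17.7) were among 3 higher in female wells; Zmat3 no longer passed with 50 kb flanks. Mdm2 (277 ± 35.5 in male, 191 ± 29.4 in female) and Sesn1 (120 ± 31.6 and 72.8 ± 25.6) were higher in male wells and turned direction with the 5 Mb offset (log2 fold changes −0.40 and −0.08). With the fusion against without it, Sesn1 was lower in male and female cells (−0.79 and −0.93, without a count filter) and Mdm2 higher (0.94 and 1.40). Of 7 glycolysis and lipid genes, 2 were higher in male and 3 in female wells. Scd2, a fatty acid desaturase, held 218 ± 22.9 in male and 72.5 ± 19.5 in female wells, Hmgcr 158 ± 27.0 and 79.2 ± 9.73, Pfkp 42.3 ± 10.7 and 152 ± 25.8, and Slc2a3, a glucose transporter, 106 ± 20.5 and 174 ± 25.4. Of 5 Wnt genes, Tcf7l2 (339 ± 52.4 in male, 216 ± 29.2 in female) and Fzd2 were higher in male and Fzd7 (142 ± 35.2 in female, 51.6 ± 18.6 in male) in female wells, and Lrp6 did not pass. In wells of the mBC files alone, Fzd2 turned to a log2 fold change of −0.02, and it no longer passed with the 5 Mb offset (adjusted p = 0.604), with DESeq2 (0.164), in windows with 50 kb flanks (0.489) or without a count filter.

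Markers of other cell types were sparse in the insertions, but so were the astrocyte identity genes, of which 7 of 20 were tested. This limits any statement about mixed cells. No oligodendrocyte, microglia or Y-linked list member had enough insertions for the test's filter. Of 15 fibroblast and pericyte markers 5 were tested. Col1a2 held 348 ± 48.5 IPM in male and 103 ± 21.5 in female wells and Acta2 251 ± 19.4 and 312 ± 32.4, while Col1a1, Col3a1 and Twist2 did not pass. Of 18 neuron markers 3 were tested, with Map2 and Syt1 higher in female and Gad2 in male wells. Of 13 endothelial markers only Esam was tested and was higher in female wells (97.2 ± 16.3 against 38.1 ± 11.5). Of the Hox genes only Hoxb3 passed the filter, with 122 ± 32.5 IPM in female wells and 0 insertions in male wells, at least 46.3-fold higher. Among 2 steroid receptors tested, Ar, the androgen receptor, was higher in male wells (110 ± 22.0 against 65.0 ± 16.1) and Nr3c1 in female wells. Of 3 BET and enhancer cofactors, Ep300 was higher in male and Cdk8 in female wells, and Arid1a did not pass. Of 4 NF-kappaB genes, Nfkb1 was higher in male wells, Cxcl1 and Vcam1 in female wells, and Tnfaip3 did not pass. Of 4 X-inactivation genes only Xist differed, and Car5b, Ftx and Jpx did not pass.

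Over all genes, 2143 of 3691 tested windows differed between male and female Brd4 wells, 1065 higher in male and 1078 in female wells. Scaling to all insertions in place of TMM shifted the median gene to 0.13 on the log2 scale and gave 1326 and 926. Of 13 lists with at least 5 tested members, camera at its preset correlation called only the patterning list, and none with an estimated correlation. Fry, which asks whether a list's genes move on balance, called 10. Median, mean and test differed in sign for cell cycle (median 0.12, fry down), Wnt (median 0.08, mean −0.17), glycolysis and lipid (median 0.07, mean −0.10) and astrocyte identity (median 0.01, mean −0.01).

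Without the Brd4 fusion, many loci already differed between the sexes. Of the regions at least 2-fold different with Brd4, 247 of 248 higher in male and 392 of 438 higher in female Brd4 wells had the same direction in unfused wells, in fits without a count filter. In that unfused fit 65.1% of 23609 shared peaks were higher in male and 34.9% in female wells, so the baselines of these 2 counts are unequal. The region in Sfta3-ps next to Nkx2-1 held 254 ± 22.1 IPM in male unfused wells and 2 insertions over all female unfused wells, and the Nkx2-1 window held 255 ± 28.1 IPM and 0 insertions. The unfused transposase also favoured male cells at Sox2ot (286 ± 38.1 against 54.6 ± 20.7 IPM), over Pou3f2, a POU factor of neural progenitors (282 ± 27.2 against 59.6 ± 20.5), at a region at the 3' end of Meis2 on chromosome 2 at 115850837 to 115863956 (432 ± 41.8 against 102 ± 58.1), within Ptprn2 (150 ± 16.1 against 4.05 ± 5.25) and 383525 bp from Pantr1 (175 ± 33.5 against 10.4 ± 10.97). It favoured female cells near Zic4 (418 ± 70.7 against 16.4 ± 7.27 IPM), between Tbc1d2b and Zic1 (1401 ± 349 against 66.9 ± 16.3 at 90685810 to 90699115, and 842 ± 223 against 24.3 ± 7.39 at 91119258 to 91128334), near Ccnh (703 ± 129 against 50.02 ± 13.7), within Clybl (494 ± 114 against 21.7 ± 11.1) and at Sp8 (505 ± 160 against 21.0 ± 11.5).

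Of 665 regions tested in unfused wells, 189 were higher in male and 177 in female wells. Scaling to all insertions shifted the median region to −0.36 on the log2 scale and gave 100 and 331 calls. The balance also depends on the count filter, with 3920 higher in male and 1522 in female wells when no filter was used and 2665 and 1173 by DESeq2. In sites found in 1 well only, without a filter, the counts were 589 and 40. Without the 2 shallowest female wells, 666 of 1341 regions passed, 348 higher in male and 318 in female wells.

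The sex difference changed with the fusion at 474 of 2876 regions, by the test of the interaction. All 10 female unfused wells come from the pBC files, while the other groups hold wells of both file sets; with pBC wells only, 264 of 3240 regions passed. The interaction is expressed as the Brd4 effect in male cells less that in female cells. Negative values mark a female excess that grew, or a male excess that shrank, with the fusion. At Six1, a homeobox gene, female and male Brd4 wells held 200 ± 35.4 and 9.59 ± 6.09 IPM and unfused wells 50.8 ± 27.2 and 29.4 ± 10.8 (interaction −3.68, SE 0.37, adjusted p = 1.78e-13). At 3110099E03Rik the Brd4 wells held 255 ± 30.4 and 77.1 ± 29.8 and the unfused wells 33.1 ± 20.8 and 66.3 ± 18.97 (−2.90, SE 0.26). Male excess of the unfused transposase shrank with the fusion over Pou3f2 (399 ± 57.0 in male, 282 ± 31.3 in female Brd4 wells; −2.07), at the 3' end of Meis2 (657 ± 39.1 and 392 ± 65.9; −1.72), near Pantr1 (285 ± 43.4 and 126 ± 23.9; −2.93) and within Tcf4 (201 ± 33.1 and 218 ± 30.4, against 140 ± 21.8 and 35.7 ± 27.7 unfused; −2.58).

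Positive interactions that the rule named lay around Zic genes and next to Six3, where the female excess was smaller with Brd4 than without it, and at Rims2. They were found near Tbc1d2b at 90685810 to 90699115 (1.59, SE 0.14), near Zic1 at 90833266 to 90842603 (1.29), at Six3os1, 664 bp from Six3 (1.65), near Zic4 (1.54) and within Clybl (1.39). In sites found in 1 well only, without a filter, the values near Zic4 and within Clybl turned to −1.29 and −2.15, and of the other named interactions only that at 3110099E03Rik still passed. Within Rims2, a presynaptic gene, male Brd4 wells held 144 ± 18.5 IPM and female ones 32.1 ± 14.7, against 62.0 ± 12.7 and 60.03 ± 24.3 unfused (1.68). Of all calls, 135 were positive and 339 negative. Scaling to all insertions shifted the median region to 0.29 and gave 579 and 222, so the balance of directions depends on the scaling. In simulated wells, 51.7% of regions with a 2-fold interaction were recovered among 2700 tested. Simulated wells were independent with a spread near counting error, while real wells varied less. The share of such interactions missed in the real wells is therefore not known.

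**Figure D3:**
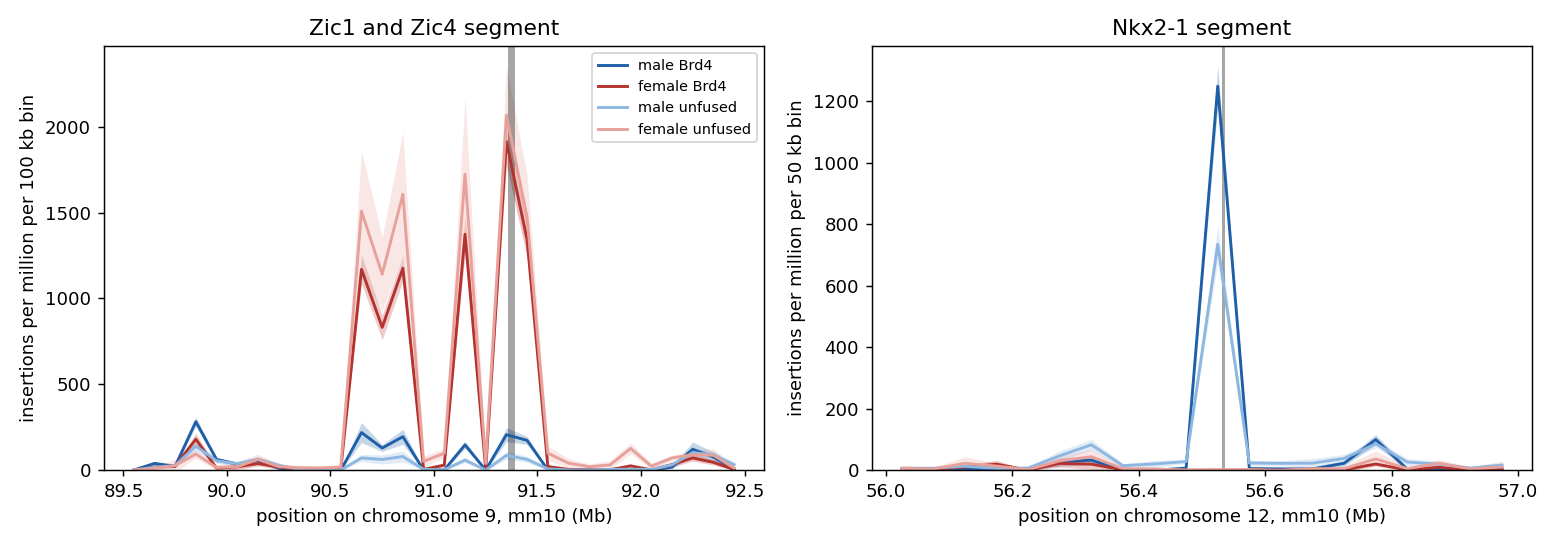
Mean IPM per bin (lines) with ± SD over wells (shading) along chromosome 9 around Zic1 and Zic4 (left, 100 kb bins) and along chromosome 12 around Nkx2-1 (right, 50 kb bins), in the 4 groups; dark bands are the genes. Female wells of both kinds rise above male wells in separate islands of dense insertions around Zic1 and Zic4, and male wells of both kinds rise next to Nkx2-1. Sparse bins between the islands were also higher in female wells. At 91000001 to 91100000, female and male wells held 98.9 ± 27.0 and 2.97 ± 3.61 IPM unfused, and 29.9 ± 9.62 and 1.65 ± 3.27 with Brd4. Past Zic4, at 91900001 to 92000000, unfused wells held 127 ± 32.0 and 5.67 ± 7.80.

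The deposited lists split the Brd4 peaks into 2679 male-biased, 2778 female-biased and 24395 shared peaks, with no overlap between the lists at 1 bp or at 50% of the shorter peak. Biased peaks were wider than shared ones, with median widths of 6268 bp, 6130 bp and 4170 bp, and 55.9%, 54.0% and 60.2% lay within a gene. The smallest peak of each biased list held 20 insertions and that of the shared list 3, so these widths are not compared at equal height. Of the 1716 and 1690 nearest genes of the biased lists, 236 appeared in both. In the authors' deposited tables, the largest corrected p was 0.0478 for male-biased and 0.04996 for female-biased peaks. All 621 male-biased peaks that could be tested between wells were called higher in male Brd4 wells, and all 605 female-biased peaks higher in female Brd4 wells. The study chose these lists on the same samples, so this is not independent evidence of their direction. In unfused wells, whose counts these lists do not hold, 98.2% of 166 tested male-biased peaks were higher in male wells and 125 passed. Of 128 tested female-biased peaks, 93.8% were higher in female unfused wells and 110 passed. Without the count filter the share was 80.1% of 2774, against 34.9% of shared peaks.

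Whole chromosomes also differed in their share of insertions. Chromosome 14 took 3.78 ± 0.0423% of insertions in male and 2.98 ± 0.0378% in female Brd4 wells, and 3.76 ± 0.0535% and 2.80 ± 0.0991% in unfused wells. Chromosome 10 took 6.44 ± 0.0893% and 5.59 ± 0.0774% with Brd4 and 7.20 ± 0.0399% and 5.11 ± 0.105% without. Chromosome 15 took 5.46 ± 0.0419% and 4.37 ± 0.0631% with Brd4. Female wells took more on chromosome 2 (8.89 ± 0.0684% against 7.98 ± 0.0541% with Brd4, 10.0 ± 0.157% against 8.001 ± 0.0421% without) and on chromosome X (3.11 ± 0.0546% against 2.75 ± 0.0582% with Brd4, 2.74 ± 0.0355% against 2.51 ± 0.0527% without). Permutation tests, exact for Brd4 wells and adjusted over chromosomes, called all 19 autosomes with Brd4 (8 higher in male, 11 in female wells) and 17 of 19 without it (7 and 10). Outside peaks, chromosome 14 took 3.97 ± 0.0884% in male and 2.75 ± 0.121% in female unfused wells.

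**Figure D4:**
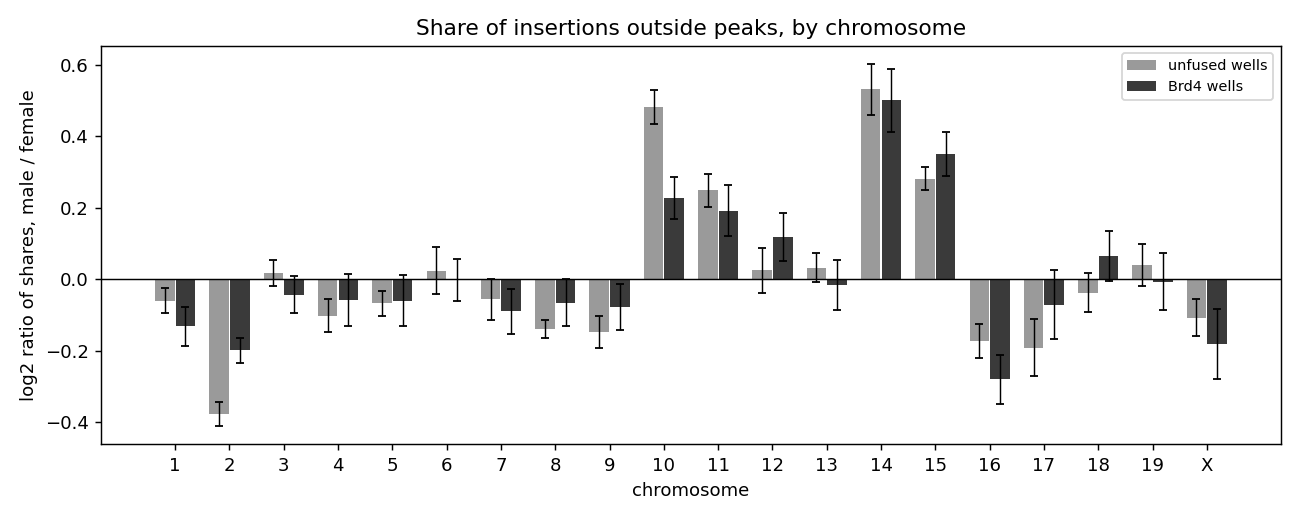
Log2 ratio of the male to the female share of insertions outside peaks, for chromosomes 1 to 19 and X, in unfused (grey) and Brd4 (black) wells. Bars are ratios of group means and error bars combine the SDs of both groups. Chromosomes 10, 11, 14 and 15 lie above 0 in both kinds of wells, with chromosome 14 at 0.53 and 0.50, and chromosomes 2 and 16 lie below 0.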

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

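The tests of the unfused preference, of a few regions on chromosome 14, of amplification as the only cause and of the Brd4 part at the Zic segment were chosen after the results they concern were seen, as were the counts of other splits; the tests of copy number, of the cultures and of amplification were written before. In 32 of 283 groups of wells tested, 1 well lay far from the others; chance gives about 5%.

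The regions at least 2-fold different between male and female Brd4 wells, among them regions near Nkx2-1, Zic1, Sp8 and Dlx1, form the first pattern. Copy number of the surrounding segment is argued against as the whole cause for these regions as a set. The flanks (20 to 500 kb) held a median log2 ratio of only 0.392 in the region's direction (quartiles 0.04 and 0.816) against 1.68 in the regions. At 143 of 686 regions, however, the flanks moved at least as far as 0.5 of the region. That median does not speak for single loci. At the Zic segment the unfused log2 ratio of female to male outside peaks was 3.97. Near Nkx2-1, at 56550001 to 56600000, unfused wells held 23.5 ± 8.79 IPM in male and 2.08 ± 6.56 in female cells. Copy number was not tested at Nkx2-1 on its own. Preference of the unfused transposase, as open chromatin would also give, stays open: 22.6% of the 438 female-higher and 5.24% of the 248 male-higher regions passed the interaction test in their direction under both scalings (median interactions in the region's direction 0.76 and 0.10 with TMM, 0.38 and 0.50 scaled to all insertions), but these regions were chosen on the same Brd4 counts. With regions chosen in Brd4 wells of the mBC files and the interaction fitted in wells of the pBC files, 8.70% of 414 female-higher and 1.45% of 275 male-higher regions passed (medians 0.69 and 0.04 with TMM, 0.25 and 0.50 scaled to all insertions), too few to argue against it, from fewer wells, though the female-higher medians lean that way. A difference between the cultures other than sex cannot be told apart from sex, because the titles name 1 culture per sex, and sex itself stays open and untested.

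Chromosome 14 took a larger share of insertions in male wells, with and without Brd4. A few regions with many insertions are argued against, since outside peaks the log2 ratio in unfused wells was 0.53. Copy number of the chromosome may account for it, as 95.8% of 24 windows of 5 Mb in unfused wells and 90.5% of 21 in Brd4 wells were higher in male wells outside peaks. The windows ranged from −0.80 to 0.84 in unfused wells, so at least 1 part of the chromosome goes the other way. No biological explanation was tested.

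The 1 Mb of chromosome 9 from position 90500001, which holds Zic1 and Zic4, took 7851 ± 501 IPM in female and 1076 ± 102 in male Brd4 wells (7.29-fold), and 9728 ± 1825 and 434 ± 57.3 in unfused wells (21.2-fold). The female excess was present without the Brd4 part, so it does not need the fusion. Whether binding directed by the Brd4 part adds to it cannot be told. The log2 ratio with Brd4 was lower than without it (difference −1.54 over all sites). However, counts of unique sites are bounded in dense regions. Female Brd4 wells were also deeper than female unfused wells (mean 132703 and 84770 insertions), which could lower the ratio. In sites found in 1 well only, the interaction near Zic4 turned to −1.29. Those near Tbc1d2b and Zic1 kept their sign at 1.42 and 1.15. Amplification as the only cause cannot be settled here. It would multiply both kinds of wells alike, while outside peaks their log2 ratios differed by 1.499 (counting error 0.30). However, peaks were called on the Brd4 insertions, so places dense in female Brd4 insertions drop out of that count. Whether unfused insertions served as a background in the peak calls is not given in the sources used here. The male Brd4 wells held only 37 insertions outside peaks (32.6 ± 19.7 IPM). Amplification may contribute, as the unfused log2 ratio outside peaks was 3.97. An active chromatin domain in the female culture would also raise both kinds of wells and was not tested.

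Chance in how these wells were divided is argued against for the counts of calls, at the number of splits drawn and if the wells are separate transfections. Splits that mix the groups put the group difference into the spread between wells, which lowers their calls. The splits set the groups against the spread between wells of a culture, so they say nothing on chance differences between cultures. In each comparison, of 100 splits of the wells into groups of the same sizes, 1 gave as many calls, the real one. The real counts and the highest of the other splits were 1653 and 0 for Brd4 regions between sexes, 366 and 0 for unfused regions between sexes, 474 and 26 for the interaction, and 2143 and 1 for gene windows. They were 1724 and 1281 for Brd4 against unfused in male cells and 1216 and 1089 in female cells. In these highest splits 15 of 19 male wells and 18 of 20 female wells stayed with their own kind, and 3 of the splits in each sex gave more than 100 calls. The highest splits thus lie close to the real one.

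The sex difference at 474 regions differed between Brd4 and unfused wells. All female unfused wells come from the pBC files, and with pBC wells of all groups 264 regions passed. The interaction values on the log2 scale at the named regions were 1.59 near Tbc1d2b, 1.29 near Zic1, 1.65 at Six3os1, 1.39 at Clybl, 1.54 near Zic4 and 1.68 at Rims2. They were −2.07 at Pou3f2, −1.72 at Meis2, −2.58 at Tcf4, −2.90 at 3110099E03Rik, −3.68 at Six1 and −2.93 near Pantr1. In sites found in 1 well only, 54 regions passed, and the values at Clybl and near Zic4 turned to −2.15 and −1.29.

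Depth set some wells apart. Male Brd4 well 1 held 94563 insertions against 125660 to 138016 in the others, and male unfused well 5 held 126690 against 186803 to 239134. Median reads per insertion were 4 in male Brd4 well 7, the merged pair, against 2 to 3, and 3 in male unfused well 2 against 1 to 2. Male unfused well 5 also stood apart with 16 Y insertions against 35 to 53, with 3.63% of insertions on chromosome 14 against 3.73% to 3.82%, and in IPM at Meis2 (529 against 376 to 451), Sp8 (47.4 against 8.69 to 26.1), 4921513I03Rik (260.5 against 165 to 207) and 3110099E03Rik (111 against 44.2 to 74.1).

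Female Brd4 well 4 held 4 Y insertions against 0 to 2 in the other female Brd4 wells, and more than they at 2 of the 12 named regions higher in male wells, with 73.8 IPM at Cyp1b1 against 15.3 to 36.3 and 16.4 at Ptprn2 against 0, while at Sfta3-ps it held 0 like the others. Female unfused well 3, with 32249 insertions, was highest at Meis2 (248 IPM against 33.1 to 124), near Tbc1d2b (2264 against 1100 to 1656), at Sp8 (899 against 311 to 596) and at Six3os1 (713 against 269 to 430). Among the other female Brd4 wells, well 9 held 40.7 IPM at Runx2 against 7.55 to 23.0, well 3 held 512 at Sema3a against 353 to 431, well 5 held 944 near Tbc1d2b against 1073 to 1213, and well 2 held 153 in the Ccnb1 window against 106 to 129.

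Among male Brd4 wells, well 7 held 434 IPM at Akap6 against 321 to 369, well 1 held 677 at Adk against 507 to 588 and 761 near 4921513I03Rik against 583 to 641, and well 2 held 414 at Sox2ot against 480 to 531. Well 5 held 23.5 at Gmds against 0 to 10.6 and 109.8 near Zic4 against 39.8 to 72.8, well 9 held 72.5 in the Eif2s3y window against 7.59 to 39.8, and well 3 held 7.82 in the Sry window, a single insertion, against 0. Among male unfused wells, well 8 held 48.2 IPM at Clybl against 5.16 to 25.1, well 6 held 125 at Adk against 164 to 201, and well 7 held 54.7 at Six1 against 16.1 to 34.6.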

How the results depend on the processing

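No paired analysis was possible because the barcodes that mark wells carry no replicate number. The file set as a block, which keeps the mBC and pBC wells apart, gave 1654 regions for Brd4 between sexes. The fits without the shallowest well of each group, without the 2 shallowest female unfused wells, at a minimum count of 2, with an offset and no filter, on sites found in 1 well only, with the merged barcodes apart and outside peaks, and DESeq2, no filter, no TMM and file sets for gene windows, were chosen after seeing the data. Of 1425 values under alternatives, 104 are counts and main differences: 64 stayed (counts within 1.5 times, others within their spread or on their side of the threshold), 39 moved and 1 no longer passed. For single genes, regions, chromosomes and lists, 1241 kept their direction and side of the threshold, 51 no longer passed, 16 newly passed and 13 had the opposite sign. Depth limits what can be tested: the default filter kept 2657 of 29852 regions for Brd4 between sexes, and looser filters tested more regions and called more.

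DESeq2, which differs in test, scaling and filter together, gave 6770 regions for Brd4 between sexes, 3838 for unfused between sexes, 2698 (972 up, 1726 down) and 2955 (1674 up, 1281 down) for Brd4 against unfused in male and female cells, 810 interactions and 4556 gene windows. With no filter on low counts the counts were 8624, 5442, 7751, 5762, 1117 and 5569, and at a minimum count of 2 they were 6015, 2792, 6971, 4641 and 1160 regions. With an offset per 5 Mb and no filter, 8443 regions differed for Brd4. Insertions with at least 2 reads, which are fewer, gave 1046 for Brd4 between sexes, 218 for unfused, 745 for female fusion and 247 interactions, and the male less female share in peaks fell to 0.0714 points and no longer passed (the cause was not tested). Tested against a fold of 1.5, 809 Brd4 regions passed. Sites found in 1 well only gave, without a filter, 1233 regions for Brd4 between sexes (381 higher in male, 852 in female wells; 322 of the 1653 calls kept), 629 unfused, 6592 male fusion, 3084 female fusion and 54 interaction regions; with the filter fewer than 50 regions were left and no value was made.

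TMM factors gave 600 male and 719 female fusion regions, since they centre the regions, and scaling to all insertions gave 801 interactions. Wells of the pBC files only gave 2705 male fusion regions and 264 interactions, and 2646 male fusion regions passed without the shallowest well of each group, as more regions were tested. Without the 2 shallowest female unfused wells 666 unfused regions passed. Gene windows of 50 kb flanks gave 5460 calls. Without a filter, 80.1% of female-biased peaks were higher in female unfused wells. Of the gene lists, 0 passed camera with the estimated correlation (1 at an unadjusted p under 0.05, the patterning list with 0.0466), 10 passed fry and 0 passed camera under the interaction (0 unadjusted), a different comparison, in which the patterning list had the opposite sign (adjusted p = 0.605).

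Reversed values, whose cause was not tested, were log2 fold changes of 0.15 near Tbc1d2b with the 5 Mb offset and 0.0801 with that offset and no filter, an offset that contains the segment's own unfused insertions. In sites found in 1 well only, the interactions were −2.15 at Clybl and −1.29 near Zic4. With the 5 Mb offset, log2 fold changes were 0.34 at Nfib, 0.39 at Cdh2, 0.0816 at Runx1, −0.34 at Rb1, −0.40 at Mdm2 and −0.0784 at Sesn1. From the regions nearest to the gene, Nfib was at 0.28, and in wells of the mBC files Fzd2 was at −0.0191.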

Other observations

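Scanned in windows of 1 Mb, chosen after seeing the data, Brd4 insertions differed between the sexes also at loci other than those named above. Among 1511 windows with at least 200 IPM in either sex, 24 were at least 4-fold higher in female and 7 in male Brd4 wells, while all male wells lay above all female wells in 316 and the reverse held in 248. The window with the highest female to male ratio, on chromosome 16 from 88000001 to 89000000, holds Grik1, a kainate receptor gene, and held 210 ± 31.1 IPM in female and 3.44 ± 4.08 in male Brd4 wells (61.1-fold), against 65.5 ± 26.2 and 14.3 ± 6.77 unfused. A window with Brinp1 on chromosome 4 held 271 ± 61.7 and 5.76 ± 7.97 IPM (47.0-fold), against 92.1 ± 54.6 and 13.6 ± 6.38 unfused. Windows with Fmn2 and Grem2, a BMP antagonist (chromosome 1, 11.7-fold), with Sema3e and Pclo (chromosome 5, 8.79-fold) and with Eya1, a transcriptional cofactor (chromosome 1, 7.88-fold), were higher in female Brd4 wells as well. These are ratios of means, and every female Brd4 well lay above every male Brd4 well in each of these 5 windows.

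At that fold, windows higher in male Brd4 wells were fewer. The highest ratio was that of the window with Nkx2-1 and Pax9 on chromosome 12 (1475 ± 92.8 against 115 ± 24.2 IPM, 12.8-fold; 5.45-fold unfused), then that of Ctnna3, an alpha-catenin gene, on chromosome 10 (209 ± 34.0 against 19.5 ± 14.5, 10.7-fold; 3.33-fold unfused). Further windows held Slc5a7 (6.27-fold), Meox2 and Dgkb (6.04-fold) and Fbn2, a fibrillin gene (4.49-fold). Of the 24 windows higher in female wells, 9 were also at least 4-fold higher in female unfused wells, and of the 7 higher in male wells, 1 was. At lower folds the unfused wells often differed as well. In each of these 7 windows every male unfused well lay above every female one, at 2.32-fold to 5.45-fold. Every female unfused well lay above every male one in the windows with Grik1, Brinp1, Sema3e and Eya1. In the window with Fmn2 the unfused wells overlapped.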
